A study of Homo sapiens with 24 samples.

How the data were processed

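RNA was measured in 24 libraries from 2 human prostate cancer cell lines, PC3 and LNCaP. Per the labels, each line was present as parental cells and as a chronic-exposure (CE) derivative, made by passaging parental cells in rising concentrations of Acetalax until they were resistant and then keeping them for 2 weeks without the drug. Each of these 4 kinds of cells was sampled without treatment (control) and after 10 µM Acetalax for 4 h, which gave 8 groups of 3 libraries. PC3 was grown in F-12 and LNCaP in RPMI-1640, both with 10% serum, so medium and line cannot be separated in comparisons across lines. The labels give 1 batch for every library. Per the labels' protocols, 800 ng of RNA was enriched for poly(A) RNA, made into strand-directional libraries and read as 100 bp paired ends on an Illumina NextSeq instrument. FastQC, STAR 2.7, RSEM and the build GRCh38 (hg38) are named in the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here, so values of antisense and overlapping genes are uncertain, as are those of near-identical copies, among which RSEM divides reads by estimation.

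The authors deposited RSEM expected counts for 60660 features in all 24 libraries, of which 10.2% of values were not whole numbers. They were rounded before testing, which moved no library total by more than 0.000125%. The authors also deposited TPM (transcript abundances scaled for gene length to a fixed total of 1000000 per library), which were used for levels and for 1 family of alternatives. In each of the 2 tables, 1 further column belonged to no library, and these 2 columns were not used. Every other column was matched to its sample by the library name in the labels. There were 0 features without a name. Feature identifiers matched GENCODE 29 in 58385 cases, and positions were taken from that release on GRCh38. Because 1233 features shared their symbol with another, each symbol in a gene list stood for the feature with the highest mean count. Totals of expected counts ranged from 40160832 to 57728014 per library. Ranges and limits given for low counts cover counting error only, because reads without molecular identifiers are not independent molecules. A fold change against a group whose 3 libraries all held 0 counts was computed against 3 counts over the group, the 95% limit that a count of 0 allows, and is given as a lower bound. Replicates were compared before averaging, and every pair within a group differed by more than sampling noise (chi-square over degrees of freedom 3.43 to 263).

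Differences were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. All adjusted p-values of genes come from this test unless another tool is named. Genes with low counts were removed with filterByExpr at a minimum count of 10. Each line was fitted on its 12 libraries, with 20049 genes tested in PC3 and 19393 in LNCaP. The differences between lines were fitted on all 24 libraries, with 21955 genes tested. The comparisons were Acetalax against control in parental and in CE cells, CE control against parental control, the difference of the Acetalax responses between CE and parental cells, and the differences of the parental responses and of the CE changes between lines. Standard errors of log2 fold changes were derived from the fold change and its quasi-likelihood F value, and 95% intervals of TRPM4 from that error and the degrees of freedom of the same test. The labels call the samples biological triplicates but name no separate cultures, so p-values measure only the spread between these samples, which may be partly technical. Groups of 3 against 3 were compared by the model across genes because 10 splits of 6 libraries cannot give a share below 0.1.

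The 31 gene lists covered TRPM channels and the SUR1 partner, sodium and potassium transport, cell volume and osmotic response, the integrated stress response, the unfolded protein response, the heat shock response, immediate early genes, NF-kB and cytokines, the interferon response, NRF2 targets, metallothioneins, p53 targets, hypoxia and glycolysis, nuclear OXPHOS genes, mitochondrially encoded genes, cholesterol synthesis, fatty acid synthesis, the cell cycle, androgen receptor targets, neuroendocrine, epithelial and mesenchymal markers, PC3 line markers, drug metabolism and efflux, cell death, ERK feedback, YAP and TAZ targets, lysosome and autophagy, cytosolic ribosomal proteins, replication-dependent histones, and fibroblast, endothelial and immune markers. Each was tested with camera (limma) against all other genes with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated from the data. Replacing fitted values by their bounds for members with a group at 0 left the list medians as printed.

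The lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took TRPM4 everywhere, the 8 largest rises and the 8 largest falls of each comparison of 2 groups (adjusted p under 0.05, no overlap between libraries, a mean of at least 5 CPM in the higher group), the 3 largest differences in each direction for the differences of responses, and up to 4 members of each list with the smallest p. Clone-based, LINC, antisense and pseudogene names were left out of the ranks, as was 1 sex-linked feature. Some genes that the rule took are not reported here. CTNNA1, VEGFA, NDRG1, CA9, DDIT3, CHAC1, KLK3, KRT8, CDH1 and VIM were, where their levels are given per group or library, chosen after their values were seen. These alternatives were DESeq2 1.42.0, median-of-ratios scaling (RLE), no low-count filter, a minimum count of 50, the replicate number as a block, limma on log2(TPM + 1) and log2(TPM + 0.1), other sets of libraries in the fit, a 2-fold threshold (log2 of 1) and leaving out each replicate in turn. Fits without libraries that stood apart were added after seeing the data. Similarity of groups was the Pearson correlation of log2(TPM + 1) over protein-coding genes with at least 1 TPM.

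The procedure was tested on data simulated from real means and library sizes. In PC3 parental (18062 genes), 81% of 100 genes changed 2-fold and 96% of 100 changed 4-fold were recovered, with 8 false calls of 186. In LNCaP parental (17648 genes) these were 80% and 97%, with 11 false calls of 191. A planted cholesterol list shift was recovered in both, with 0 of 30 others called. Genes were drawn without correlation, so real list calls stay unchecked. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and figures. Imaging, blotting, viability, xenograft and tissue data of the series were not analysed.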

Results

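To follow gene expression during Acetalax exposure and after resistance, RNA was sequenced from PC3 and LNCaP cells. PC3 is an androgen-independent prostate cancer line from a bone metastasis, and LNCaP is an androgen-sensitive line from a lymph node metastasis. Acetalax (oxyphenisatin acetate) is a former laxative, and TRPM4 encodes a calcium-activated channel that conducts monovalent cations such as sodium. The series describes both lines as high in TRPM4 and presents TRPM4 as a marker of the drug's activity. Parental cells of each line and cells labelled as its chronic-exposure (CE) derivative were measured without drug and after 4 h with 10 µM Acetalax, with 3 libraries in each of 8 groups. PC3 CE and LNCaP CE stand for the libraries so labelled. Mean totals of expected counts per library were 42747404 and 44554471 in PC3 parental control and Acetalax libraries, and 47837084 and 46815539 in LNCaP parental. In PC3 CE they were 48873868 and 53013411, and in LNCaP CE 47852046 and 54579866. All levels are means ± SD in TPM and all fold changes are log2 ± standard error, each over 3 libraries or 3 against 3.

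TRPM4 (ENSG00000130529.16, protein coding, GRCh38 chromosome 19, 49157741 to 49211836, plus strand) stood at 45.3 ± 4.62 TPM in PC3 parental controls and at 98.9 ± 7.85 TPM in LNCaP parental controls. In the CE controls it stood at 17.4 ± 1.78 TPM for PC3 and 9.42 ± 0.478 TPM for LNCaP. Libraries of a group were alike, with Pearson correlations of log2(TPM + 1) of at least 0.993 within 5 of the 8 groups. Lower values occurred in LNCaP parental controls (lowest pair 0.971), LNCaP parental Acetalax (0.969) and PC3 CE Acetalax (0.953). Across groups, over 13105 protein-coding genes, the PC3 CE and LNCaP CE controls correlated at 0.933. PC3 CE correlated with PC3 parental at 0.657, LNCaP CE with LNCaP parental at 0.722, and the parental lines with each other at 0.715. These correlations are across genes, which are not independent replicates.

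**Figure D1:**
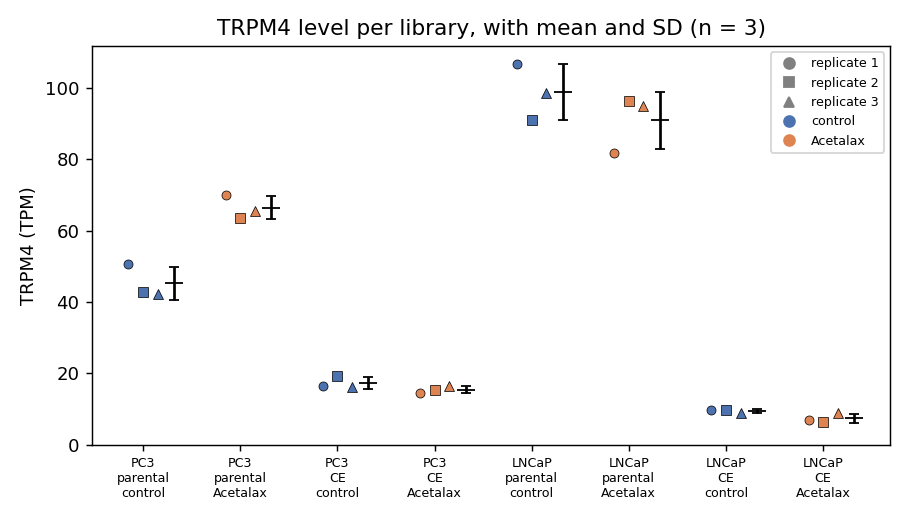
TRPM4 level in TPM (vertical axis) in each of the 24 libraries (points), by group (horizontal axis), with mean and SD. Group means run from 98.9 TPM in LNCaP parental controls and 66.4 TPM in PC3 parental Acetalax to 7.45 TPM in LNCaP CE Acetalax.

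**Figure D2:**
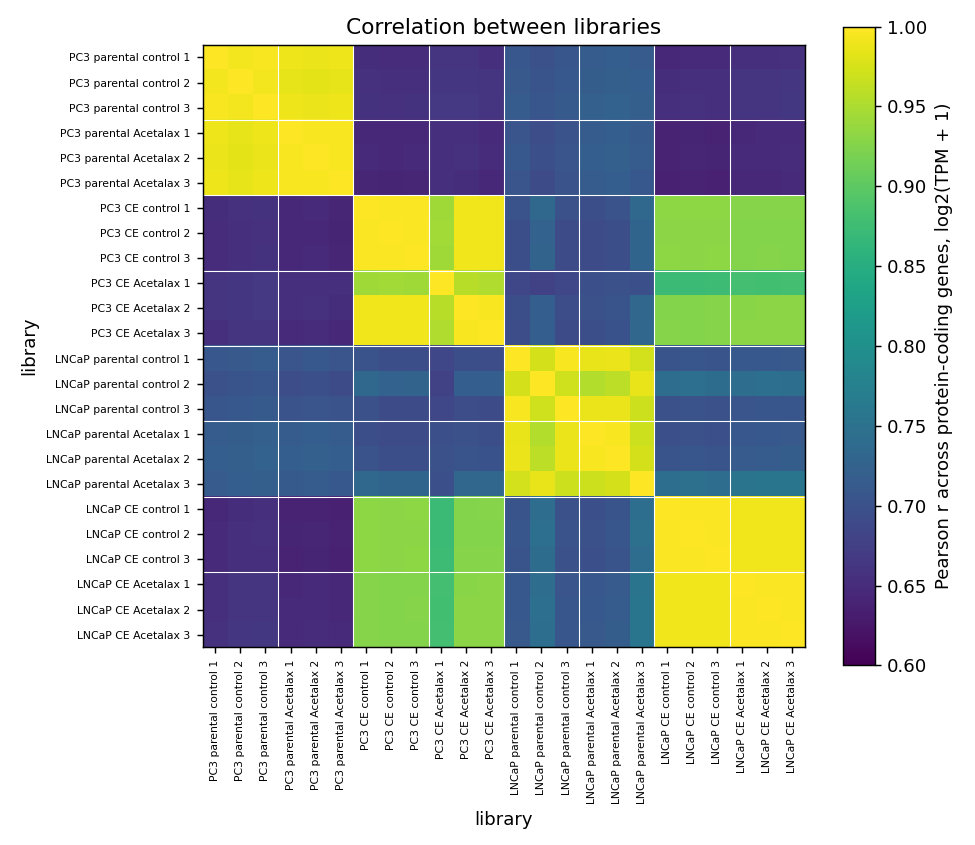
Pearson correlation of log2(TPM + 1) between every pair of the 24 libraries, drawn as a colour scale from 0.6 to 1. The CE libraries of both lines form 1 block (0.933 between the CE control groups), while each CE group is paler against the parental line of its label (0.657 and 0.722).

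The first comparison asked how PC3 parental cells responded to 4 h of Acetalax. TRPM4 rose from 45.3 ± 4.62 to 66.4 ± 3.20 TPM, a log2 fold change of 0.58 ± 0.08 (1.5-fold, adjusted p = 0.00193), and all 3 treated libraries lay above all 3 controls. Heat shock and histone genes made up the 8 largest rises by the ranking. HSPA6 (ENSG00000173110.8, chromosome 1, 161524540 to 161526910), a strictly inducible HSP70 chaperone, went from 5.78 ± 0.556 to 284 ± 19.4 TPM (log2 5.64 ± 0.19, adjusted p = 4.78e-08). The HSP40 co-chaperone DNAJB1 (chromosome 19, 14514770 to 14529770) went from 131 ± 2.16 to 917 ± 55.6 TPM (2.94 ± 0.07, adjusted p = 9.84e-10). HSPA1A and HSPA1B, near-identical inducible HSP70 genes whose reads cannot be fully told apart, rose by 3.82 ± 0.42 and 3.53 ± 0.46 (adjusted p = 0.000734 and 0.00159). Among the falls, ID1, an inhibitor of basic helix-loop-helix factors, went from 230 ± 24.4 to 73.7 ± 6.10 TPM (-1.67 ± 0.12, adjusted p = 8.25e-05), and SMG8, a factor of nonsense-mediated decay, changed by -1.74 ± 0.21 (adjusted p = 0.000922). LRIG3, DDX28, CGRRF1 and ZNF823 were lower by log2 values of -1.46, -1.50, -1.57 and -1.58.

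By list, 6 of 31 lists passed in PC3 parental cells. In the heat shock list, 6 of 18 tested members rose and 1 fell (8 and 1 adjusted over the list alone), including HSPB1 at 1.63 ± 0.25, with a median log2 of 0.36 (adjusted p = 2.44e-13, and adjusted p = 0.560 with an estimated correlation). Of 25 interferon response genes, 4 fell and none rose (8 fell adjusted over the list alone), among them the RNA sensor DDX58 at -0.63 ± 0.11, with a median of -0.35 (adjusted p = 5.15e-05, and adjusted p = 0.589 with an estimated correlation). Of 13 mitochondrially encoded genes, 3 fell (5 adjusted over the list alone), including MT-ND3 at -1.22 ± 0.21 and MT-CO1 at -0.91 ± 0.17, with a median of -0.47 (adjusted p = 4.02e-05, and adjusted p = 0.593 with an estimated correlation). The share of counts from mitochondrial genes was 5.96 ± 1.08% in controls and 4.12 ± 0.526% in treated libraries. In the cholesterol synthesis list 4 of 24 members rose, also 4 adjusted over the list alone, led by the sterol sensor INSIG1 at 1.97 ± 0.31. The median was 0.32 (adjusted p = 0.00151, and adjusted p = 0.981 with an estimated correlation). Of 21 replication-dependent histones 5 rose (8 adjusted over the list alone), among them H2BC11 at 1.42 ± 0.21 and H2AC8 at 2.97 ± 0.47, with a median of 0.75 (adjusted p = 4.57e-06, and adjusted p = 0.593 with an estimated correlation). Histone copies share sequence and their mRNAs mostly lack poly(A) tails, so these values are uncertain in poly(A)-selected libraries. Mesenchymal markers, with 2 of 23 higher and 1 lower (4 and 1 adjusted over the list alone) and COL6A2 at 0.59, had a median of 0.20 (adjusted p = 0.0460, and adjusted p = 0.560 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.0996), control 3 (0.0503), Acetalax 1 (0.0887) or Acetalax 2 (0.0612).

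The test called 1564 of 20049 genes (7.80%), 697 higher and 867 lower, of which 134 changed at least 2-fold. Of the 16 largest changes by the ranking, H2BC7, H2BC18 and MT-ND6 lost their call without any 1 of the 6 libraries (adjusted p = 0.0534 to 0.102, 0.111 to 0.164 and 0.0565 to 0.171), and HPS6 without Acetalax 1 (0.0669) or Acetalax 2 (0.0617). Left-out libraries moved the count to 931 (without control 1), 778 (control 2), 706 (Acetalax 1), 572 (Acetalax 2) and 810 (Acetalax 3), and to 5595 without PC3 CE Acetalax 1, which shares the fit and was left out after seeing the data. With only the 6 libraries compared it was 4790.

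The same question was put to LNCaP parental cells. TRPM4 stood at 98.9 ± 7.85 TPM before and 91.0 ± 8.05 TPM after Acetalax, and its log2 fold change of 0.08 ± 0.10 (95% interval -0.14 to 0.30) did not pass (adjusted p = 0.795). By limma on log2(TPM + 1) and log2(TPM + 0.1) the fold change was -0.12 and also did not pass. Sterol genes were among the rises. MSMO1, which encodes a sterol demethylating enzyme (ENSG00000052802.13, chromosome 4, 165327623 to 165343160), went from 40.01 ± 4.56 to 269 ± 73.3 TPM (log2 2.79 ± 0.16, adjusted p = 7.12e-06), and INSIG1 rose by 2.02 ± 0.25 (adjusted p = 0.000734). HSPA6 rose by 4.49 ± 0.89, from 0.603 ± 0.247 to 13.4 ± 11.1 TPM (adjusted p = 0.0110, but 0.0677 and 0.0666 by limma on TPM), and CREBRF, a regulator of stress and metabolism, by 2.75 ± 0.54 (adjusted p = 0.0102). The matricellular gene CCN1 and the AP-1 gene JUN rose by 2.58 ± 0.14 and 2.17 ± 0.27 (adjusted p = 7.12e-06 and 0.000815). The growth regulator MYC fell from 148 ± 15.2 to 19.2 ± 12.3 TPM (-2.82 ± 0.39, adjusted p = 0.00143). Falls were also seen for HPS6 (-2.22 ± 0.22, adjusted p = 0.000211) and ZNF552 (-1.90 ± 0.15, adjusted p = 6.70e-05).

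Of 31 lists, 10 passed in LNCaP parental cells. In the cholesterol synthesis list 14 of 23 members rose (16 adjusted over the list alone) and none fell, with HMGCS1 at 1.47 ± 0.11 and IDI1 at 1.28 ± 0.11 beside MSMO1. Its median was 0.56 (adjusted p = 1.69e-27, and adjusted p = 0.00114 with an estimated correlation). Of 13 NF-kB and cytokine genes 5 rose, also adjusted over the list alone, including TNFAIP3 at 1.86 ± 0.22, IL11 at 1.37 and NFKBIA at 0.57 ± 0.11. The median was 0.57 (adjusted p = 5.35e-05, and adjusted p = 0.0221 with an estimated correlation). Among 29 immediate early genes 10 rose and 1 fell (11 and 1 adjusted over the list alone), with JUNB at 2.00 ± 0.19 and ZFP36 at 1.75 ± 0.17. The median was 0.75 (adjusted p = 2.96e-09, and adjusted p = 0.234 with an estimated correlation). The lysosome and autophagy list had 4 of 24 higher (10 adjusted over the list alone) and a median of 0.32 (adjusted p = 2.23e-06, and adjusted p = 0.568 with an estimated correlation).

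Another 6 lists passed at smaller medians and lost their call when 1 library was left out. The integrated stress response had 4 of 25 higher, also adjusted over the list alone, with the amino acid enzyme ASNS at 0.36 (median 0.15, adjusted p = 0.00717, and adjusted p = 0.834 with an estimated correlation), and its adjusted p was 0.345 without control 2. ASNS itself lost its call without a low-count filter (adjusted p = 0.0505). Heat shock genes (3 of 18 higher, 3 adjusted over the list alone, DNAJB1 at 1.66 ± 0.32, median 0.18) had an adjusted p of 0.0154 (adjusted p = 0.694 with an estimated correlation), which became 0.0754 without control 1 and 0.219 without control 3. Fatty acid synthesis (4 of 16 higher, 4 adjusted over the list alone, FASN at 0.75 ± 0.12, median 0.10) had an adjusted p of 0.0154 (adjusted p = 0.694 with an estimated correlation), and 0.130 without control 2 or 0.0527 without Acetalax 2. Androgen receptor targets (2 of 24 lower, 2 adjusted over the list alone, C1orf116 at -1.26 ± 0.13, median -0.13) had an adjusted p of 0.0495 (adjusted p = 0.447 with an estimated correlation), and 0.102, 0.129 and 0.207 without control 1, control 3 and Acetalax 3. With RLE scaling that adjusted p was 0.0509. ERK feedback genes (4 of 16 lower, 6 adjusted over the list alone, SPRY2 at -1.13 ± 0.11, median -0.22) had an adjusted p of 0.0316 (adjusted p = 0.234 with an estimated correlation), and 0.0594, 0.107, 0.0857 and 0.0732 without control 1, control 3, Acetalax 1 and Acetalax 3 (0.319 without control 2 and Acetalax 3 together). Ribosomal protein genes (0 of 32 past the threshold, 0 adjusted over the list alone, median 0.12) had an adjusted p of 0.0146 (adjusted p = 0.874 with an estimated correlation), and 0.219 without control 3 or 0.697 without Acetalax 3.

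In LNCaP parental cells 1629 of 19393 genes passed (8.40%), 781 higher and 848 lower, 453 of them by at least 2-fold. With only the 6 libraries compared in the fit the count was 111, of which 109 were among the 1629. Control 2 and Acetalax 3 stood apart from the other 4 libraries. VEGFA stood at 512.5, 53.9 and 573 TPM in controls 1 to 3 and at 746, 606 and 76.3 TPM in Acetalax 1 to 3. NDRG1, another hypoxia-inducible gene, stood at 603, 52.4 and 681.5 TPM and at 581, 443 and 42.4 TPM, and the stress gene DDIT3 at 264, 26.4 and 341 TPM and at 274, 231 and 51.4 TPM. The count was 1016 without Acetalax 1, 943 without Acetalax 2, 2607 without Acetalax 3, and 5328 without control 2 and Acetalax 3 together, a fit added after seeing the data. The named genes TRIM49D1 and FDXACB1 lost their call without Acetalax 1 (adjusted p = 0.0766 and 0.0637), TRIM49D1 also without control 1 (0.0546) and FDXACB1 without Acetalax 2 (0.0789).

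**Figure D3:**
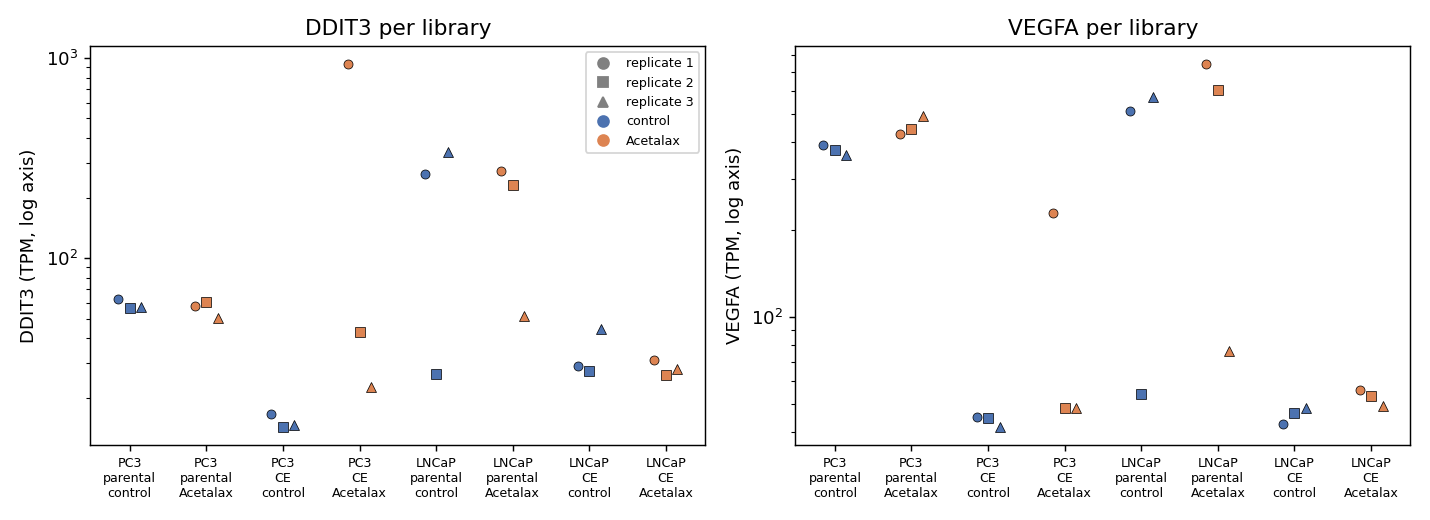
DDIT3 and VEGFA levels in TPM (log axis) in each library, by group. Control 2 and Acetalax 3 of LNCaP parental cells lie below their group (VEGFA 53.9 and 76.3 TPM), and replicate 1 of PC3 CE Acetalax lies above its group (DDIT3 936 TPM against 43.0 and 22.7 TPM).

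Whether the parental lines responded differently was tested directly. The TRPM4 responses differed by -0.50 ± 0.13 (LNCaP minus PC3, adjusted p = 0.0245), a call lost without PC3 parental control 2 (adjusted p = 0.0757), PC3 Acetalax 1 (0.0630) or 2 (0.0639), or LNCaP parental control 1 (0.0697), Acetalax 1 (0.0706) or 2 (0.0550), and lost without a low-count filter (0.134). In 4 lists the responses differed with the preset correlation, each at adjusted p = 0.752 with an estimated correlation. Cholesterol synthesis genes differed by a median of 0.42 (2 of 24 members higher in LNCaP, 4 adjusted over the list alone, adjusted p = 0.00155) and lysosome and autophagy genes by 0.34 (2 of 24, 2 adjusted over the list alone, adjusted p = 0.00141). Immediate early genes differed by a median of 0.30 (5 of 29 higher and 1 lower, the same counts adjusted over the list alone, adjusted p = 0.00563), with an adjusted p of 0.189 without LNCaP control 2. Histones differed by -0.77 (2 of 24, 4 adjusted over the list alone, adjusted p = 0.00182). SLC43A3, a purine transporter gene, differed by 5.50 (adjusted p = 0.000734), at 0.0233 and 0.537 TPM in LNCaP control and Acetalax and 29.1 and 24.8 TPM in PC3, but did not pass by limma on TPM (0.0892 and 0.0953). Fitted differences of this kind rest on a group near 0 and depend on the prior count.

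Across 17663 genes tested in both lines, the parental responses correlated at r = 0.0755 (Spearman 0.152), and these comparisons shared no libraries. Genes higher in both numbered 76, where independent lists would give 29.8, genes lower in both 136 (40.4), and genes called in opposite directions 81 (69.6). INSIG1 rose in both (1.97 and 2.02), as did HSPA6, DNAJB1 and IER5 (1.40 and 1.01), and DDX28 and HPS6 fell in both, HPS6 with the loss in PC3 without Acetalax 1 (adjusted p = 0.0669) or 2 (0.0617). In all, 1114 genes differed in response between the lines (698 higher and 416 lower in LNCaP), 404 of them by at least 2-fold, with 692 without PC3 Acetalax 2 and 4320 without the 3 libraries of both lines that stood apart (added after seeing the data).

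The next comparison set PC3 CE controls against PC3 parental controls, to ask how the libraries labelled CE differed without drug. TRPM4 was lower in the libraries labelled CE, at 17.4 ± 1.78 against 45.3 ± 4.62 TPM (log2 -1.49 ± 0.08, 2.80-fold lower, adjusted p = 9.69e-09), in 3 of 3 libraries. Epithelial genes were among the largest falls. KRT7, a simple epithelial keratin (ENSG00000135480.16, chromosome 12, 52232520 to 52252186), went from 4187 ± 341 to 0.767 ± 0.456 TPM (log2 -13.63 ± 0.67, adjusted p = 4.06e-09), and the iron-binding secreted protein gene LCN2 from 664 ± 55.3 TPM to 0 in every library (at least 1.317e+04-fold lower). S100A9, a calcium-binding inflammatory protein gene at 1501 ± 61.0 TPM in parental cells, had 3 counts in CE against 52696 (ratio interval 1.027e-05 to 0.0001455). Conversely, the Wnt antagonist gene DKK2 was at 137 ± 4.09 TPM in CE and at 0 in parental controls (at least 1.216e+04-fold higher), and the pituitary factor POU1F1 was at 122 ± 3.54 TPM (at least 4341-fold higher). TYRP1, a melanin synthesis gene (chromosome 9, 12685439 to 12710290), stood at 380 ± 9.82 TPM with 79154 counts against 1 count in parental controls (ratio interval 1.243e+04 to 2.735e+06).

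Of 31 lists, 7 passed for PC3 CE. All 21 epithelial markers fell, also adjusted over the list alone, with KRT18 at -5.90 ± 0.15, CLDN4 at -7.99 ± 0.21 and ST14 at -9.90 ± 0.28. The median was -7.99 (adjusted p = 1.60e-20, and adjusted p = 0.0953 with an estimated correlation). Of 23 NF-kB and cytokine genes 20 fell and 1 rose, the same adjusted over the list alone, with CXCL1 at -8.24 ± 0.20 and IL1B at -9.83 ± 0.26. The median was -4.83 (adjusted p = 4.89e-08, and adjusted p = 0.0953 with an estimated correlation). Of 24 sodium and potassium transport genes 17 fell and 4 rose, the same adjusted over the list alone, among them the sodium pump subunits ATP1B1 at -6.16 ± 0.10 and ATP1B3 at 2.05 ± 0.06 and the epithelial sodium channel gene SCNN1A at -6.47 ± 0.24. The median was -1.58 (adjusted p = 9.29e-05, and adjusted p = 0.0953 with an estimated correlation). In the interferon list 18 of 25 fell and 4 rose (18 and 5 adjusted over the list alone), with IFIT2 at -4.95 ± 0.11 and BST2 at 7.03 ± 0.26. The median was -1.92 (adjusted p = 0.00273, and adjusted p = 0.619 with an estimated correlation). All 31 cell cycle genes were higher, also adjusted over the list alone, with TYMS at 4.31 ± 0.23 and MCM5 at 3.62 ± 0.20. The median was 2.65 (adjusted p = 8.16e-05, and 0.773 with an estimated correlation). Markers of the PC3 line fell in 13 of 16 cases and rose in 3, the same adjusted over the list alone, with ITGB4 at -10.56 ± 0.30 and CD44 at -8.67 ± 0.28 against VIM at 6.09 ± 0.19. The median was -6.47 (adjusted p = 2.44e-06, and adjusted p = 0.279 with an estimated correlation). YAP and TAZ targets fell in 12 of 18 cases and rose in 5, the same adjusted over the list alone. The median was -1.02 (adjusted p = 0.0195, and adjusted p = 0.763 with an estimated correlation).

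In PC3 CE, 15530 of 20049 genes passed (77.5%), 7722 higher and 7808 lower, 10922 of them by at least 2-fold. CTNNA1 (alpha-catenin, ENSG00000044115.21, chromosome 5, 138610967 to 138935034), which is known to be deleted in PC3, stood at 1.04 ± 0.696 TPM in parental controls and 170 ± 3.14 TPM in CE controls. In LNCaP parental controls it stood at 186.5 ± 42.3 TPM. This gene was chosen after its values were seen. The name CE is taken from the labels alone, and the PC3 values argue against descent of the PC3 CE cells from PC3 with changes in transcription alone.

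**Figure D4:**
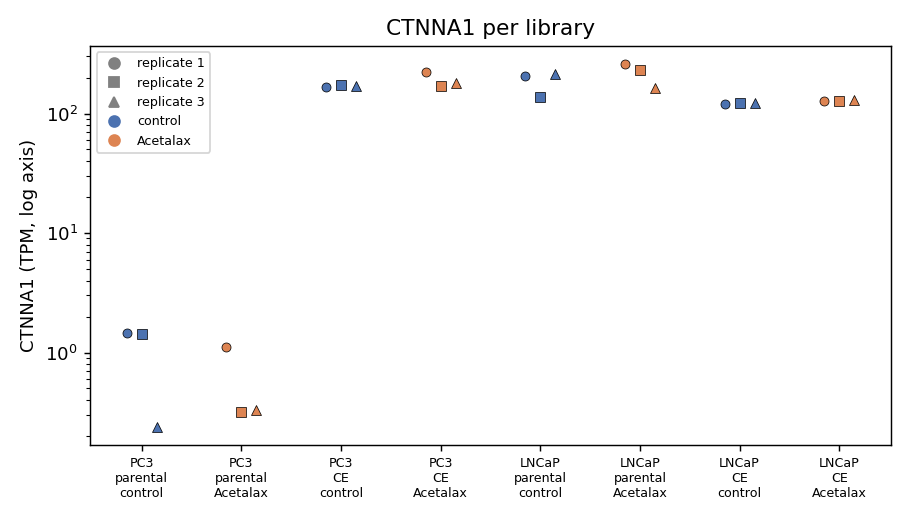
CTNNA1 level in TPM (vertical log axis) in each of the 24 libraries (points), by group (horizontal axis). Means are 1.04 TPM in PC3 parental and 170 TPM in PC3 CE controls.

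LNCaP CE controls were compared with LNCaP parental controls in the same way. TRPM4 was at 9.42 ± 0.478 against 98.9 ± 7.85 TPM (log2 -2.60 ± 0.11, 6.06-fold lower, adjusted p = 2.61e-09), lower in 3 of 3 libraries. On TPM the fall was larger, at -3.26 by limma on log2(TPM + 1) and -3.38 on log2(TPM + 0.1). The secreted muscle and bone factor gene OSTN (ENSG00000188729.6, chromosome 3, 191199241 to 191265615) rose by 14.90 ± 0.62, to 1580 ± 77.3 TPM (adjusted p = 2.83e-09), and the guidance factor gene SEMA3A was at least 3791-fold higher. LIN28A, an RNA-binding pluripotency factor gene, had 51869 counts against 2 (ratio interval 7177 to 2.141e+05) and 148 ± 1.07 TPM. TRGC1, a T-cell receptor gamma constant gene known to be transcribed in androgen-responsive prostate cells, fell from 96.5 ± 1.39 TPM to 0 (at least 8142-fold). UGT2B15, at least 5052-fold lower, belongs to a family of near-identical copies and is uncertain in its share of reads.

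Of 31 lists, 11 passed for LNCaP CE, and 5 of these also with an estimated correlation. Androgen receptor targets fell in 21 of 24 cases and rose in 1 (21 and 2 adjusted over the list alone), with FOLH1 at -7.70 ± 0.15 and C1orf116 at -11.15 ± 0.23. The median was -7.17 (adjusted p = 6.71e-11, and adjusted p = 0.0154 with an estimated correlation). Epithelial markers fell in 19 of 21 cases, also adjusted over the list alone, with KRT18 at -6.18 ± 0.12 and GRHL2 at -13.31 ± 0.27. The median was -8.51 (adjusted p = 8.59e-12, and adjusted p = 0.0273 with an estimated correlation). Interferon response genes rose in 21 of 26 cases and fell in 3, the same adjusted over the list alone, with IFITM1 at 7.86 ± 0.16 and BST2 at 9.04 ± 0.21. The median was 2.83 (adjusted p = 1.02e-05, and adjusted p = 0.0273 with an estimated correlation). ERK feedback genes rose in 11 of 16 cases and fell in 2, the same adjusted over the list alone, with ETV4 at 10.97 ± 0.13 and DUSP6 at 8.87 ± 0.18. The median was 4.00 (adjusted p = 0.000455, and adjusted p = 0.0487 with an estimated correlation). Fibroblast, endothelial and immune markers rose in 6 of 9 cases and fell in 1, the same adjusted over the list alone, with the matrix genes COL3A1 at 9.81 ± 0.12 and DCN at 12.18 ± 0.27 and the endothelial gene VWF at -10.12 ± 0.44. The median was 3.42 (adjusted p = 0.00382, and adjusted p = 0.0496 with an estimated correlation).

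The other 6 lists passed only with the preset correlation. Mesenchymal markers rose in 16 of 22 cases and fell in 3, the same adjusted over the list alone, with CDH2 at 10.92 ± 0.23 and ZEB1 at 12.55 ± 0.37. The median was 5.42 (adjusted p = 1.64e-05, and adjusted p = 0.123 with an estimated correlation). Markers of the PC3 line rose in 8 of 15 and fell in 2, the same adjusted over the list alone, with AXL at 11.18. The median was 1.95 (adjusted p = 0.0178, and adjusted p = 0.291 with an estimated correlation). Cell cycle genes rose in 21 of 31 cases, also adjusted over the list alone, with CCNE1 at 2.15. The median was 1.55 (adjusted p = 0.0178, and adjusted p = 0.822 with an estimated correlation). In this list LNCaP parental control 2, 1 of the 3 reference libraries, and Acetalax 3 lay at least 1.22 log2 units above the other 4 parental libraries. Metallothioneins fell in 4 of 5 cases (4 fell and 1 rose adjusted over the list alone), with MT2A at -3.55 ± 0.19 (median -3.44, adjusted p = 0.0298, and adjusted p = 0.358 with an estimated correlation), and lost the call without the LNCaP parental libraries control 2 and Acetalax 3 (adjusted p = 0.137) and without a low-count filter (0.0665). Drug metabolism and efflux genes fell in 17 of 25 cases and rose in 5 (18 and 5 adjusted over the list alone), with UGT2B17 at -12.31 and CYP1B1 at 10.47 ± 0.33. The median was -3.41 (adjusted p = 0.0136, and adjusted p = 0.291 with an estimated correlation). Replication-dependent histones fell in 18 of 22 and rose in 1, the same adjusted over the list alone, with H3C10 at -3.09 ± 0.14. The median was -2.76 (adjusted p = 0.00477, and adjusted p = 0.268 with an estimated correlation). The share of counts from these histones was 0.0559, 0.0191 and 0.0597% in LNCaP parental controls 1 to 3. The same parental libraries, control 2 and Acetalax 3, lay below the other 4 by at least 0.32 in the mesenchymal list and 0.29 in the drug metabolism list, and above them by 0.21 in the interferon list.

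In LNCaP CE, 14570 of 19393 genes passed (75.1%), 6965 higher and 7605 lower, 10194 of them by at least 2-fold. KLK3, which encodes prostate-specific antigen, stood at 4399 ± 1283 TPM in parental and 0.777 TPM in CE controls.

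CE changes (CE minus parental, descent not shown) were then compared. For TRPM4, LNCaP minus PC3 was -1.14 ± 0.13 (adjusted p = 1.75e-07), and -1.92 by limma on log2(TPM + 1). Across 17663 genes the CE changes correlated at r = 0.554 (Spearman 0.473), with 4181 genes higher in both (2716 for independent lists), 3637 lower in both (2318) and 2632 in opposite directions (5022). The difference itself passed for 12475 of 21955 genes, 5634 higher and 6841 lower in LNCaP, 9429 of them by at least 2-fold. Interferon response genes differed by a median of 4.73 (24 of 26 higher in LNCaP, 25 adjusted over the list alone, adjusted p = 5.80e-20, and adjusted p = 0.00256 with an estimated correlation). PC3 line markers differed by 9.44 (15 of 16 higher and 1 lower, adjusted p = 3.58e-15, and 0.00441 with an estimated correlation). ERK feedback genes differed by 4.10 (11 and 2 of 16, adjusted p = 1.19e-10, and 0.00256 with an estimated correlation). NF-kB and cytokine genes differed by 6.51 (17 of 23, adjusted p = 1.29e-05, and 0.0234 with an estimated correlation). Mesenchymal markers differed by 2.47 (15 and 1 of 23, adjusted p = 3.28e-08, and 0.0146 with an estimated correlation). Androgen receptor targets differed by -4.62 (2 higher and 19 lower of 24, adjusted p = 1.61e-10, and 0.00441 with an estimated correlation). Adjusted over the list alone, these counts were the same, except 2 and 20 in the last. With CE controls alike (0.933), PC3 line markers and androgen receptor targets would differ here anyway if they separate the parental lines.

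In another 5 lists the difference of the CE changes passed only with the preset correlation. Sodium and potassium transport genes differed by a median of 0.51 (14 higher and 4 lower of 25, adjusted p = 0.00149, and adjusted p = 0.0799 with an estimated correlation), and YAP and TAZ targets by 1.31 (10 and 5 of 18, adjusted p = 0.000287, and adjusted p = 0.437 with an estimated correlation). NRF2 targets differed by 0.93 (12 and 4 of 21, adjusted p = 0.0473, and 0.0501 without PC3 CE control 2) and p53 targets by -0.99 (3 and 11 of 22, adjusted p = 0.0372), both at adjusted p = 0.566 with an estimated correlation. Hypoxia and glycolysis genes differed by -1.83 (2 and 19 of 30, adjusted p = 0.0473, and adjusted p = 0.917 with an estimated correlation), with adjusted p = 0.0688 and 0.0768 without LNCaP parental control 1 and control 3. Counts adjusted over the list alone were the same in these 5 lists. Beside the hypoxia list, LNCaP parental control 2 held VEGFA at 53.9 TPM against 512.5 and 573 TPM in controls 1 and 3.

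Acetalax was also given to the CE cells. In PC3 CE, TRPM4 stood at 17.4 ± 1.78 TPM before and 15.5 ± 0.916 TPM after the drug (log2 -0.02 ± 0.08, 95% interval -0.20 to 0.15, adjusted p = 0.887) and did not pass, with a log2 of 0.00497 without Acetalax 1. Immediate early genes, which respond to growth factor and stress signals within minutes, were among the largest rises. FOS (ENSG00000170345.10, chromosome 14, 75278774 to 75282230) went from 7.10 ± 0.136 to 313 ± 330 TPM (5.69 ± 0.66, adjusted p = 0.000861), EGR1 from 11.1 to 274 ± 283 TPM (4.70 ± 0.61, adjusted p = 0.00158) and EGR3 from 1.49 to 39.4 ± 48.4 TPM (4.80 ± 0.78, adjusted p = 0.00486). All 3 treated libraries lay above all 3 controls, although replicate 1 lay far above replicates 2 and 3. The falls included the interferon-induced gene IFIT5 (-1.73 ± 0.29, adjusted p = 0.00562), TTC30B (-1.39 ± 0.21, adjusted p = 0.00353) and BEND3 (-1.48 ± 0.23, adjusted p = 0.00443). Replicate 1 stood apart in stress and hypoxia genes, with DDIT3 at 936, 43.0 and 22.7 TPM in Acetalax replicates 1 to 3, VEGFA at 228, 48.5 and 48.4 TPM, CHAC1 at 161, 13.9 and 8.17 TPM and CA9 at 39.5, 2.47 and 0.75 TPM.

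Of 31 lists, 13 passed in PC3 CE with the drug. Of 29 immediate early genes 25 rose (26 adjusted over the list alone), with CCN1 at 2.55 ± 0.22 and ZFP36 at 2.77 ± 0.30. The median was 2.55 (adjusted p = 1.49e-33, and adjusted p = 0.225 with an estimated correlation). ERK feedback genes rose in 7 of 16 cases (10 rose and 1 fell adjusted over the list alone), with SPRY4 at 0.97 ± 0.07 and DUSP6 at 1.25 ± 0.15. The median was 0.65 (adjusted p = 4.66e-09, and adjusted p = 0.159 with an estimated correlation). NF-kB and cytokine genes rose in 8 of 23 and fell in 1 (12 and 1 adjusted over the list alone), with PTGS2 at 1.68 ± 0.23 and TNFAIP2 at -0.62 ± 0.10. The median was 0.80 (adjusted p = 2.33e-05, and adjusted p = 0.225 with an estimated correlation). YAP and TAZ targets rose in 6 of 18 and fell in 1 (9 and 2 adjusted over the list alone, median 0.59, adjusted p = 0.000176, and adjusted p = 0.665 with an estimated correlation). Cell volume and osmotic response genes rose in 5 of 21 cases (6 adjusted over the list alone), with the osmotic factor NFAT5 at 0.94 and the amino acid transporter gene SLC38A2 at 0.53. The median was 0.22 (adjusted p = 0.0243, adjusted p = 0.225 with an estimated correlation, and adjusted p = 0.0661 without Acetalax 3). Lysosome and autophagy genes rose in 3 of 24 (7 adjusted over the list alone), with NEU1 at 1.18 (median 0.23, adjusted p = 0.00259, and adjusted p = 0.665 with an estimated correlation), and mesenchymal markers in 4 of 23, also adjusted over the list alone. The median was 0.24 (adjusted p = 0.0113, and adjusted p = 0.276 with an estimated correlation). Acetalax replicate 1 lay above replicates 2 and 3 by medians of 1.48 in the immediate early list, 0.68 in YAP and TAZ targets, 0.58 in ERK feedback, 0.51 in lysosome and autophagy genes, 0.39 in NF-kB and cytokine genes, 0.28 in mesenchymal markers and 0.05 in cell volume genes.

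The integrated stress response list had 4 of 25 higher (21 adjusted over the list alone) and a median of 1.59 (adjusted p = 3.54e-06, and adjusted p = 0.696 with an estimated correlation), with DDIT3 at 4.55 ± 1.12, which lost its call without any 1 of the 3 controls (adjusted p = 0.119 to 0.121). Hypoxia and glycolysis genes had 3 of 30 higher (9 adjusted over the list alone) and a median of 0.87 (adjusted p = 0.000215, adjusted p = 0.696 with an estimated correlation, and adjusted p = 0.0755 without Acetalax 1). Cell cycle genes had 0 of 31 past the threshold, also adjusted over the list alone, and a median of -0.41 (adjusted p = 3.29e-05, adjusted p = 0.696 with an estimated correlation, and adjusted p = 0.0606 without Acetalax 1). Nuclear OXPHOS genes had 0 of 37, also adjusted over the list alone, and a median of -0.15 (adjusted p = 0.00458, and adjusted p = 0.801 with an estimated correlation), and without Acetalax 1 the direction turned (adjusted p = 0.944). In these 4 lists replicate 1 of Acetalax stood apart, by medians of 2.74, 1.66, -1.42 and -0.60 from replicates 2 and 3. Histones rose in 6 of 21 (12 adjusted over the list alone, median 1.01, adjusted p = 2.78e-05, and adjusted p = 0.665 with an estimated correlation), with 0.0160, 0.00588 and 0.00631% of counts in Acetalax replicates 1 to 3. Ribosomal protein genes had 0 of 32 past the threshold, also adjusted over the list alone, and a median of 0.18 (adjusted p = 0.000176, and adjusted p = 0.696 with an estimated correlation).

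In all, 1623 of 20049 genes passed (8.10%), 935 higher and 688 lower, 546 of them by at least 2-fold. With only the 6 libraries compared in the fit the count was 162, of which 161 were among the 1623. The count was 526, 547 and 501 without controls 1, 2 and 3, 3352 without Acetalax 1 and 2669 without Acetalax 3. The named genes ATF3, DUOX2, EGR2, EGR4, KLHDC7B, IFIT1, FDXACB1 and CCDC184 each lost their call without any 1 of the 3 controls (adjusted p = 0.101 to 0.106, 0.127 to 0.144, 0.0559 to 0.0732, 0.15 to 0.159, 0.133 to 0.146, 0.0713 to 0.0877, 0.101 to 0.141 and 0.107 to 0.141). DUOX2 and KLHDC7B also lost it without Acetalax 1 (0.0680 and 0.0919), and CCDC184 without Acetalax 2 (0.0620) or 3 (0.0523).

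In LNCaP CE, TRPM4 stood at 9.42 ± 0.478 TPM before and 7.45 ± 1.29 TPM after Acetalax (log2 -0.20 ± 0.10, 95% interval -0.43 to 0.02, adjusted p = 0.312) and did not pass, but passed when only these 6 libraries were fitted (-0.21, adjusted p = 0.0306). BCL6, a transcriptional repressor gene (ENSG00000113916.18, chromosome 3, 187721377 to 187745727), rose from 5.02 ± 0.572 to 21.2 ± 0.839 TPM (2.31 ± 0.12, adjusted p = 1.41e-05), and MSMO1 from 30.2 ± 2.14 to 121 ± 1.88 TPM (2.13 ± 0.15, adjusted p = 8.43e-05). BIRC3, an inhibitor of apoptosis induced by NF-kB, rose by 2.55 ± 0.20 (adjusted p = 0.000116) and AOC3 by 2.39 ± 0.25 (adjusted p = 0.000577). Among the falls, CCDC71 changed by -1.61 ± 0.24 (adjusted p = 0.00304) and CCDC8 by -1.53 ± 0.18 (adjusted p = 0.00116).

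Of 31 lists, 11 passed in LNCaP CE with the drug. Cholesterol synthesis genes rose in 13 of 23 cases (16 adjusted over the list alone), with IDI1 at 1.01 ± 0.10 beside MSMO1. The median was 0.65 (adjusted p = 2.70e-23, and adjusted p = 0.00230 with an estimated correlation). NF-kB and cytokine genes rose in 6 of 13 and fell in 1 (8 and 1 adjusted over the list alone), with NFKBIA at 2.00 ± 0.11, TNFAIP3 at 2.88 ± 0.25 and TNF at 4.44 ± 0.74. The median was 0.54 (adjusted p = 3.24e-09, and adjusted p = 0.00230 with an estimated correlation). Immediate early genes rose in 6 of 29 cases (10 rose and 1 fell adjusted over the list alone), with ZFP36 at 1.84 ± 0.17 and CCN1 at 1.37 ± 0.14. The median was 0.63 (adjusted p = 3.27e-07, and adjusted p = 0.315 with an estimated correlation). The integrated stress response rose in 4 of 25, also adjusted over the list alone, with MTHFD2 at 0.48 ± 0.07 and ASNS at 0.45 ± 0.08. The median was 0.22 (adjusted p = 0.00165, and adjusted p = 0.558 with an estimated correlation). Lysosome and autophagy genes rose in 4 of 24, also adjusted over the list alone (median 0.16, adjusted p = 0.000421, and adjusted p = 0.550 with an estimated correlation), NRF2 targets in 3 of 21 (4 adjusted over the list alone, median 0.18, adjusted p = 0.00207, and adjusted p = 0.315 with an estimated correlation) and fatty acid synthesis genes in 5 of 16 (6 adjusted over the list alone, median 0.25, adjusted p = 0.00431, and adjusted p = 0.499 with an estimated correlation). Ribosomal protein genes had 1 of 32 higher, also adjusted over the list alone (median 0.22, adjusted p = 3.27e-07, and adjusted p = 0.558 with an estimated correlation), and nuclear OXPHOS genes 0 of 37, also adjusted over the list alone. The median was 0.19 (adjusted p = 0.00167, and adjusted p = 0.716 with an estimated correlation). Cell volume and osmotic response genes rose in 2 of 21 and fell in 1 (4 and 1 adjusted over the list alone, median 0.21, adjusted p = 0.0438, and adjusted p = 0.499 with an estimated correlation), with adjusted p = 0.0621, 0.0767 and 0.0806 without control 1, control 2 and Acetalax 3. The unfolded protein response had 3 of 20 higher, also adjusted over the list alone (median 0.08, adjusted p = 0.0452, and adjusted p = 0.550 with an estimated correlation), with adjusted p = 0.0621, 0.0683, 0.0548 and 0.0610 without control 1, control 2, Acetalax 2 and Acetalax 3.

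Here 1421 of 19393 genes passed (7.33%), 642 higher and 779 lower, 352 of them by at least 2-fold. The count was 576, 579 and 571 without controls 1, 2 and 3 and 579, 549 and 522 without Acetalax 1, 2 and 3, 6802 without LNCaP parental control 2 and Acetalax 3, which share the fit, and 7952 with only the 6 libraries compared. CREBRF lost its call without any 1 control (adjusted p = 0.0502 to 0.0547), FOS without any 1 of the 6 libraries (0.0883 to 0.128), and CTSK without control 1 (0.0696), control 3 (0.0641) or Acetalax 3 (0.0511).

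Whether CE cells answered the drug differently from parental cells was tested as a difference of responses. In PC3 the TRPM4 response was lower in CE, by -0.60 ± 0.11 (adjusted p = 0.00923). HSPA6 differed by -5.80 ± 0.29 (adjusted p = 2.78e-06), at 0.697 and 0.597 TPM in CE control and Acetalax and 5.78 and 284 TPM in parental cells, and HSPA1B by -3.75 ± 0.62 (adjusted p = 0.00502). The heat shock list differed by a median of -0.70 (4 of 18 lower, 7 lower and 1 higher adjusted over the list alone, adjusted p = 4.68e-11, and adjusted p = 0.317 with an estimated correlation). Immediate early genes differed by 2.16 (14 of 29 higher, 22 adjusted over the list alone, adjusted p = 3.64e-17, and adjusted p = 0.463 with an estimated correlation), ERK feedback genes by 0.62 (7 of 16, 10 adjusted over the list alone, adjusted p = 2.77e-08, and adjusted p = 0.15 with an estimated correlation) and NF-kB and cytokine genes by 0.51 (7 higher and 1 lower of 23, 9 and 1 adjusted over the list alone, adjusted p = 0.00450, and adjusted p = 0.566 with an estimated correlation). Mitochondrially encoded genes differed by 0.71 (2 of 13, 6 adjusted over the list alone, adjusted p = 0.000108, and adjusted p = 0.730 with an estimated correlation), YAP and TAZ targets by 0.69 (4 of 18, 6 higher and 1 lower adjusted over the list alone, adjusted p = 0.00199, and adjusted p = 0.973 with an estimated correlation) and cell volume genes by 0.25 (5 of 21, 6 adjusted over the list alone, adjusted p = 0.00450, and adjusted p = 0.15 with an estimated correlation). In CE Acetalax replicate 1 the immediate early list lay 1.48 above replicates 2 and 3, YAP and TAZ targets 0.68, ERK feedback 0.58, NF-kB and cytokine genes 0.39, mitochondrially encoded genes 0.21, cell volume genes 0.05 and the heat shock list -0.63 away.

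Another 4 lists differed in PC3 with few or no members past the threshold, each at adjusted p = 0.973 with an estimated correlation. The integrated stress response differed by a median of 1.40 (0 of 25, adjusted p = 0.00235, and 0.742 without CE Acetalax 1), and hypoxia and glycolysis by 0.84 (1 higher and 1 lower of 30, 0 and 1 adjusted over the list alone, adjusted p = 0.0135, 0.281 without CE Acetalax 1 and 0.0641 without parental control 3). Cell cycle genes differed by -0.49 (0 of 31, adjusted p = 0.000177). Ribosomal protein genes differed by 0.15 (0 of 32, adjusted p = 0.0491), with 0.0625 under RLE scaling and 0.472, 0.172, 0.0556, 0.206, 0.163 and 0.0960 without parental control 3, parental Acetalax 1, parental Acetalax 3, CE control 2, CE Acetalax 1 and CE Acetalax 3. In the first 3 of these lists CE Acetalax 1 stood apart, by medians of 2.74, 1.66 and -1.42 from replicates 2 and 3. The responses of PC3 parental and CE cells correlated at r = 0.0451 across 20049 genes (Spearman 0.0600), and at 0.0289 without CE Acetalax 1, with 43 genes higher in both (32.5 for independent lists), 84 lower in both (29.8) and 129 opposite (64.4). The difference passed for 1613 genes, 925 higher and 688 lower in CE, 521 of them by at least 2-fold. The count was 978 and 1067 without parental controls 1 and 2, 813, 773 and 983 without parental Acetalax 1, 2 and 3, 825, 888 and 795 without CE controls 1, 2 and 3, and 4593 without CE Acetalax 1.

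In LNCaP the TRPM4 responses of CE and parental cells did not differ past the threshold (-0.28 ± 0.14, adjusted p = 0.490). The responses correlated at r = 0.196 across 19393 genes (Spearman 0.306), with 225 genes higher in both (25.9 for independent lists), 300 lower in both (34.1) and 25 opposite (59.4), and CD14 rose by 2.93 in both. C1orf116, an androgen-regulated gene, differed by 3.91 ± 0.30 (adjusted p = 0.000337), at 75.9 and 28.2 TPM in parental control and Acetalax and 0.04 and 0.163 TPM in CE. FGF18 differed by -4.05 ± 0.62 (adjusted p = 0.0138), but not past the threshold by limma on TPM (0.0834 and 0.0527). The heat shock list differed by a median of -0.26 (1 of 18 lower, 2 adjusted over the list alone, adjusted p = 0.0131, and adjusted p = 0.813 with an estimated correlation), with adjusted p = 0.0607 and 0.125 without parental control 1 and control 3. ERK feedback genes differed by 0.31 (2 of 16 higher, 4 adjusted over the list alone, adjusted p = 0.00334, and adjusted p = 0.0990 with an estimated correlation), with adjusted p = 0.179 without parental control 2 and Acetalax 3 together. In those libraries VEGFA stood at 53.9 and 76.3 TPM, against 512.5 and 573 TPM in the other controls and 746 and 606 TPM in the other Acetalax libraries.

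The LNCaP difference passed for 244 genes, 111 higher and 133 lower in CE, 97 of them by at least 2-fold. The count was 101 and 543 without parental controls 1 and 2, 128, 107 and 801 without parental Acetalax 1, 2 and 3, 73, 70 and 79 without CE controls 1, 2 and 3, and 74, 78 and 64 without CE Acetalax 1, 2 and 3. Without parental control 2 and Acetalax 3 together it was 3911.

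A further 4 lists passed in no comparison of 2 groups. Of the TRPM channels and the SUR1 partner, 1 rose and 1 fell of 8 with Acetalax in PC3 parental cells (2 and 2 adjusted over the list alone, adjusted p = 0.559), and in LNCaP CE against parental 2 rose and 6 fell of 9 (median -2.60, adjusted p = 0.133), with TRPM8 at -13.08 and TRPM2 at -9.52. In PC3 CE, 3 rose and 3 fell of 8 (adjusted p = 0.907), with TRPM3 at 11.93 ± 0.33 and TRPM2 at -6.36. Of p53 targets, 15 rose and 3 fell of 22 in PC3 CE (median 1.05, adjusted p = 0.0561) and 5 rose and 6 fell in LNCaP CE (adjusted p = 0.786). Of neuroendocrine markers, 8 rose and 3 fell of 11 in LNCaP CE (median 4.33, adjusted p = 0.0520), with SOX2 at 10.03, and 6 rose and 3 fell of 10 in PC3 CE (adjusted p = 0.482). Of cell death genes, 9 rose and 13 fell of 26 in PC3 CE (adjusted p = 0.112), with GSDMD at -8.55 and CASP4 at -8.56, and 11 rose and 10 fell in LNCaP CE (adjusted p = 0.972).

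**Figure D5:**
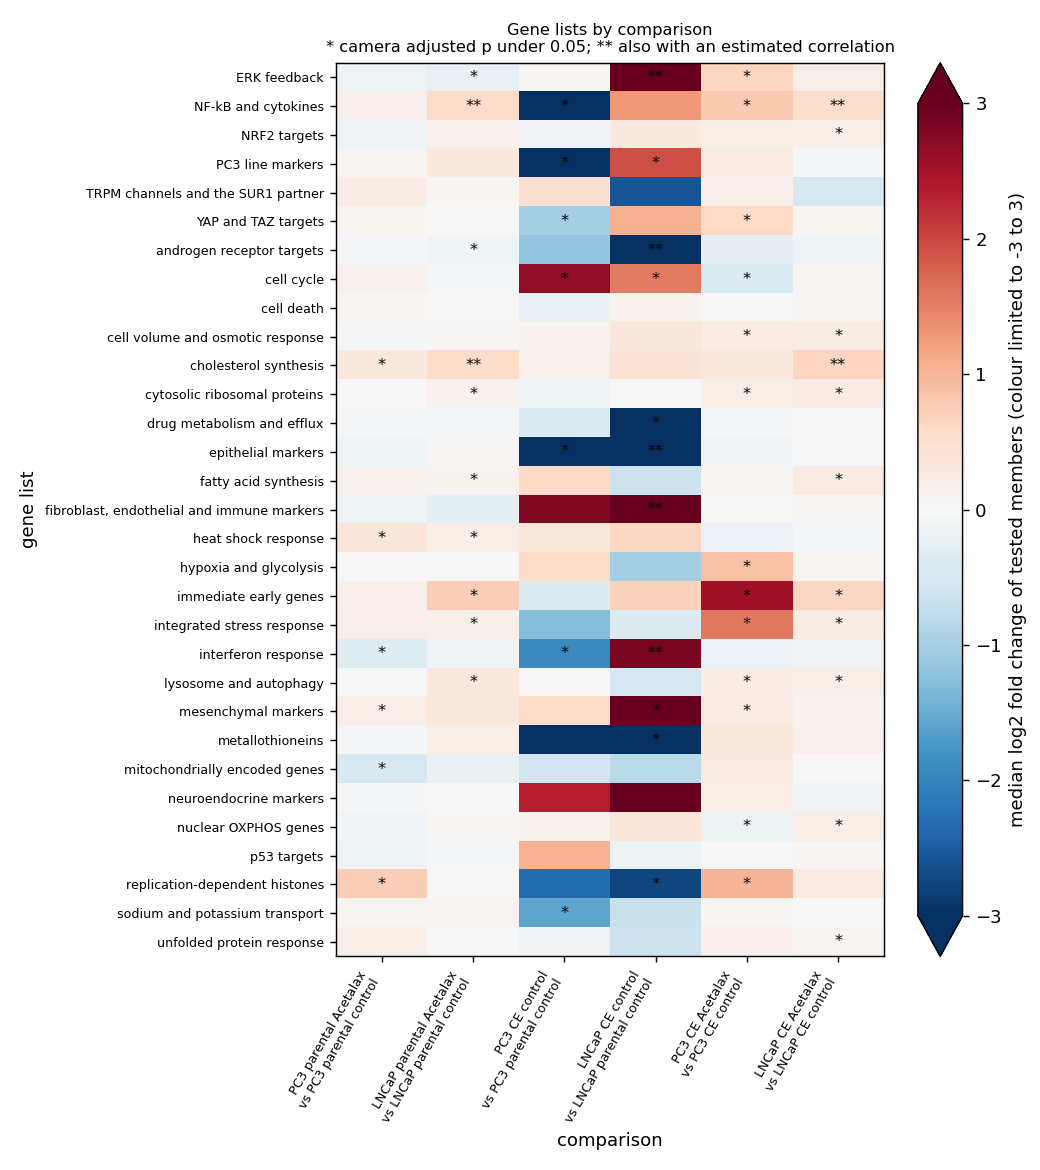
Median log2 fold change of the 31 gene lists (vertical) in the 6 comparisons of 2 groups (horizontal), with colours limited to 3 in either direction. A single asterisk marks lists past the camera test with the preset correlation and a double asterisk lists also past it with an estimated correlation, such as cholesterol synthesis in LNCaP parental (median 0.56) and LNCaP CE (0.65) cells with Acetalax.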

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

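Among the tests given here, those of CTNNA1, of the correlation between CE groups, of mixture with parental cells, of replicate 1 of PC3 CE Acetalax and of the hypoxia list in LNCaP parental libraries were chosen after the result was seen, as were fits without libraries that stood apart.

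The libraries labelled CE differed from the parental line of their label at most genes and resembled each other. Descent of the PC3 CE cells from PC3 with changes in transcription alone is argued against by CTNNA1, a gene known to be deleted in PC3, at 221 times the parental level in CE (6 against 6 libraries), while no such test is reported for LNCaP CE cells, whose descent from LNCaP stays open. A mixture of parental cells with other cells is argued against by the genes marking the parental line, whose median level in CE was 0.494% of parental for PC3 and 0.117% for LNCaP, although 15 and 10 of 50 markers exceeded 5%. What also stays open is a shared origin of the cells labelled PC3 CE and LNCaP CE that is not their labelled parent, which may account for their correlation of 0.933 against 0.657 and 0.722 with the parental lines, and is a hypothesis found and tested on the same data. Given the CTNNA1 values, differences between PC3 CE and PC3 parental cells cannot be taken as adaptation to the drug, whether or not an origin is shared. This includes the differences between their responses. With a shared origin the same would hold for LNCaP. Comparisons within CE cells do not rest on descent. Their fits share the spread with the parental libraries, however, and their counts moved when only the CE libraries compared were fitted, as given below.

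Replicate 1 of the PC3 CE Acetalax libraries stood apart from replicates 2 and 3. RNA of parental PC3 cells in that library is argued against by the parental marker genes, whose median excess over the other replicates was 0.130% of the parental level (quartiles -0.029 and 0.79). A stronger stress response in that culture may account for it: the integrated stress response list lay 2.74 log2 units above the other replicates, with all 25 genes higher. In the same library the hypoxia list lay 1.66 above, the cell cycle list -1.42 and the cholesterol list -1.64 away, and ribosomal protein genes 0.14. The cause of such a response was not tested.

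Control replicate 2 and Acetalax replicate 3 of LNCaP parental cells stood apart from the other 4 libraries. A swap of their labels is argued against by the cholesterol synthesis list, in which each library lay with its labelled group by a gap of 0.78, and CE cells in these libraries by a CE marker share of 0.00619%. Both tests were chosen before their results. A lower hypoxic response in those cultures may account for the pattern, as both lay below all other libraries by at least 1.88 log2 units in the hypoxia list (means 8.20, 6.28 and 8.31 in controls 1 to 3 and 8.17, 8.17 and 6.27 in Acetalax 1 to 3). Both also lay below the others in 14 of the 31 lists and above in 4, with the cell cycle list above by 1.22, so culture density or medium stays open and was not tested.

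Other splits of the libraries were counted for each number of genes. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real and highest other counts were 1564 and 0 (PC3 parental Acetalax, 1 split as large), 1629 and 2197 (LNCaP parental Acetalax, 2 splits as large), 15530 and 0 (PC3 CE, 1 split), 14570 and 0 (LNCaP CE, 1 split), 1623 and 1 (PC3 CE Acetalax, 1 split) and 1421 and 0 (LNCaP CE Acetalax, 1 split). The count of 2197 came from the split that put LNCaP parental controls 1 and 2 with Acetalax 3, which points to the structure of those libraries. For the differences, 100 of 200 possible splits were run within a line and 80 of 200 between lines. Each set held the split with 1 arm's labels exchanged, which gives the sum of both effects. These numbers of splits and that inclusion were set after a smaller draw had been seen. Shares were under 0.05, but only the real and exchanged splits kept groups unmixed, so chance stays open. In PC3, 2 of 100 reached the real 1613 (highest other 1695, the exchanged split). In LNCaP, 3 of 100 reached 244, the others being the exchanged split (2796) and 1 with 792 that put parental control 2 and Acetalax 3 on one side. Between the parental responses 3 of 80 reached 1114, the others being the exchanged split (2144) and 1 with 1166. The split with 1166 also put LNCaP parental control 2 and Acetalax 3 on the same side. Between the CE changes 2 of 80 reached 12475 (highest other 16330, the exchanged split).

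The following effects differed between groups in the test of the difference itself. Between PC3 CE and parental responses (CE minus parental), 1613 genes differed, with TRPM4 at -0.60, CSF2 at 5.23, HSPA6 at -5.80 and HSPA1B at -3.75. CSF2 was at 0.11 and 1.54 by limma on log2(TPM + 1) and log2(TPM + 0.1) and did not pass (adjusted p = 0.721 and 0.0659). EGR2 at 5.22, NR4A3 at 4.07 and EVA1C at -3.63 also differed, but lost their call when any of several single libraries was left out (adjusted p = 0.0661 to 0.108, 0.0667 to 0.105 and 0.0560 to 0.103). List medians differed by 0.25 (cell volume and osmotic response), 1.40 (integrated stress response), -0.70 (heat shock), 2.16 (immediate early genes), 0.51 (NF-kB and cytokines), 0.84 (hypoxia and glycolysis), 0.71 (mitochondrially encoded genes), -0.49 (cell cycle), 0.62 (ERK feedback), 0.69 (YAP and TAZ targets) and 0.15 (ribosomal proteins). Of these 11 lists 0 passed with an estimated correlation, and without PC3 CE Acetalax 1 the integrated stress response (adjusted p = 0.742), hypoxia (0.281) and ribosomal protein (0.163) calls were lost.

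Between LNCaP CE and parental responses 244 genes differed, with ZNF813 at 5.09, C9orf64 at 4.86, C1orf116 at 3.91 and FGF18 at -4.05. The C1orf116 value rests on CE levels near 0. By limma on log2(TPM + 1) and log2(TPM + 0.1), ZNF813 was at 0.38 and 1.03 (adjusted p = 0.177 and 0.0982) and FGF18 at -0.56 and -1.66 (0.0834 and 0.0527), and neither passed. HSPA6 at -6.36 and IAH1 at -4.78 lost their call in 10 of the 12 fits without 1 library (adjusted p = 0.0722 to 0.119 and 0.0614 to 0.212). The heat shock median differed by -0.26 and that of ERK feedback by 0.31, and 0 of these 2 lists passed with an estimated correlation. Between the parental responses (LNCaP minus PC3) 1114 genes differed, with TRPM4 at -0.50, SLC43A3 at 5.50, ADAMTS14 at -5.43 and PRDM8 at -3.32. The TRPM4 call was lost (-0.49 to -0.43) without PC3 parental control 2, LNCaP parental control 1, or Acetalax 1 or 2 of either line. By limma on TPM the calls of PRDM8 (-0.07 and -0.74, adjusted p = 0.933 and 0.485) and SLC43A3 (0.76 and 2.38, 0.0892 and 0.0953) were lost with either pseudocount, and that of ADAMTS14 (-0.86, 0.0646) with 0.1. CALB1 at 5.23 and SYCE3 at -4.47 lost their call in 11 and 5 of 12 such fits (adjusted p = 0.0637 to 0.134 and 0.0507 to 0.134). List medians differed by 0.30 (immediate early genes), 0.42 (cholesterol synthesis), 0.34 (lysosome and autophagy) and -0.77 (histones), and 0 of these 4 lists passed with an estimated correlation.

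Between the CE changes (LNCaP minus PC3) 12475 genes differed, with TRPM4 at -1.14, SEMA3A at 18.73, COL6A3 at 17.88, ADPRH at 17.07, MARK1 at -20.09 and TRGC1 at -19.62, fitted values that rest on groups near 0 and depend on the prior count. List medians differed by 0.51 (sodium and potassium transport), 6.51 (NF-kB and cytokines), 4.73 (interferon response), 0.93 (NRF2 targets), -0.99 (p53 targets), -1.83 (hypoxia and glycolysis), -4.62 (androgen receptor targets), 2.47 (mesenchymal markers), 9.44 (PC3 line markers), 4.10 (ERK feedback) and 1.31 (YAP and TAZ targets), and 6 of these 11 lists passed also with an estimated correlation.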

How the results depend on the processing

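The fits without libraries that stood apart, TRPM4 with other sets of libraries, and the correlations with 1 library left out were added after seeing the data. Counts for CE against parental cells and for their difference between lines stayed within 1.5 times under every alternative run. Each fit shared 1 spread per gene over its groups, although the groups differed in noise between replicates. Chi-square over degrees of freedom was 170.5 for LNCaP parental controls 1 and 2 and 3.43 for LNCaP CE controls 1 and 3. A shared spread can make p-values too small in noisy groups and too large in even ones, so counts are not directly comparable between comparisons. Counts of the other comparisons moved as follows, and the cause was not tested except where fewer libraries or a stricter threshold shows it. DESeq2 gave 2701 (PC3 parental Acetalax), 2778 (LNCaP parental), 3075 (PC3 CE), 2875 (LNCaP CE), 2779 (PC3 difference), 1076 (LNCaP difference) and 1816 (line difference). The 2-fold threshold gave 134, 453, 546, 352, 521, 97 and 404 in that order. Without a low-count filter, which tests more genes, the counts were 895 (LNCaP CE Acetalax), 126 (LNCaP difference) and 701 (line difference). On TPM, limma gave 1007 (PC3 parental) and 942 (PC3 difference) with a pseudocount of 0.1, and 450 (LNCaP difference) with 1. The z score of separate fits gave 1916 (line difference). With only the 6 libraries of the groups compared the counts were 4790 (PC3 parental), 111 (LNCaP parental), 162 (PC3 CE) and 7952 (LNCaP CE). Without PC3 CE Acetalax 1 they were 5595 (PC3 parental), 3352 (PC3 CE) and 4593 (PC3 difference), without LNCaP parental control 2 and Acetalax 3 they were 5328 (LNCaP parental), 6802 (LNCaP CE) and 3911 (LNCaP difference), and without all 3 the line difference was 4320. Leaving out 1 library at a time gave 572 to 1152 (PC3 parental), 943 to 2607 (LNCaP parental), 501 to 3352 (PC3 CE Acetalax), 522 to 579 (LNCaP CE Acetalax), 773 to 4593 (PC3 difference), 64 to 801 (LNCaP difference) and 692 to 1442 (line difference).

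With the replicate number as a block the counts were 1082 (LNCaP parental), 983 (PC3 CE Acetalax), 834 (LNCaP CE Acetalax), 1006 (PC3 difference) and 55 (LNCaP difference), and 1075, 15350, 14093, 983 and 12360 (PC3 parental, both CE changes, line difference, CE difference) within 1.5 times. The block changed no TRPM4 call, and among lists it ended androgen receptor targets (adjusted p = 0.0772) and ERK feedback (0.0858) in LNCaP parental cells. Libraries with the same number share only a number: in no comparison did all same-number correlations exceed 0.1 (LNCaP parental 0.41, -0.49 and -0.59).

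TRPM4 kept its direction in PC3 parental cells and in both CE changes. In LNCaP parental cells its log2 fold change, not past the threshold, was -0.12 and -0.12 on log2(TPM + 1) and log2(TPM + 0.1). In PC3 CE with Acetalax it was 0.00497 without Acetalax 1 (-0.0573 to 0.00497 over left-out libraries), and in LNCaP CE with Acetalax -0.21 (adjusted p = 0.0306) with only the 6 libraries. The line difference of its response was -0.49 without a low-count filter (adjusted p = 0.134) and -0.58 to -0.43 over left-out libraries. Correlations of responses over only genes past the threshold were 0.246 (parental lines), 0.141 (PC3) and 0.425 (LNCaP), with a minimum count of 50 they were 0.215 (LNCaP) and 0.591 (CE changes), and over left-out libraries they were 0.0524 to 0.0922, 0.0289 to 0.0623, 0.156 to 0.201 and 0.542 to 0.558. Values of the other sign were seen for SULT1A1 in PC3 parental (-0.00518 and -0.00929), TIGAR (-0.42 and -0.44) and CFLAR (-0.00166 and -0.00168) in PC3 CE with Acetalax on TPM with pseudocounts of 1 and 0.1. Nuclear OXPHOS genes in PC3 CE with Acetalax turned without Acetalax 1 (adjusted p = 0.944, and 3.77e-06 to 0.944 over left-out libraries). Of 778 gene calls, 16 were lost with RLE, 109 without a filter, 113 with the block, 0 of 766 with DESeq2 and 127 and 130 with limma, plus 3 in each that took the other sign and did not pass. A minimum count of 50 ended 1 of 771 calls. Over all fits without 1 library, 1010 of 6090 gene calls and 43 of 684 list calls were lost and 1 list call was reversed. Of 86 list calls, 71 were lost with an estimated correlation, 39 in fry's test of one direction and 17 in its test of either direction, 2 with RLE, 1 without a filter and 2 with the block. Totals of 40160832 to 57728014 counts per library limit folds of genes at 0 counts to lower bounds.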

Other observations

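No test was added for this part, and the levels of KRT8, CDH1 and VIM were chosen after their values were seen.

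The epithelial genes KRT8 and CDH1 were lower and VIM was higher in the libraries labelled CE of both lines. KRT8 stood at 441 and 409 TPM in PC3 and LNCaP parental controls and at 4.03 and 0.630 TPM in the CE controls, and the cell adhesion gene CDH1 at 159 and 171 TPM against 0.423 and 0.157 TPM. VIM, an intermediate filament gene of mesenchymal cells, stood at 27.2 and 6.02 TPM against 1972 and 4128 TPM. The mesenchymal list as a whole did not pass in PC3 CE (12 of 23 higher and 11 lower, adjusted p = 0.808), where CDH2 changed by -1.46 ± 0.08. FOLH1, which encodes prostate-specific membrane antigen, differed from the labelled parent by 7.58 ± 0.27 in PC3 CE and -7.70 ± 0.15 in LNCaP CE. HSPA1A changed by -8.34 in PC3 CE without drug, with reads shared by its near-identical copy HSPA1B. The share of counts from mitochondrial genes was 3.76% in PC3 CE controls and 1.42% in LNCaP CE controls, against 5.96% and 3.50% in the parental controls.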
